A study of Mus musculus with 6 samples.

How the data were processed

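Mucosa of the glandular stomach from 3 wild-type and 3 A4gnt-null mice of 5, 10 and 50 weeks was compared, with 1 mouse and 1 array per genotype and age. Per the labels, RNA was purified on columns and labelled with Cy3 by a Quick Amp kit. Per the file headers, the fluorescence intensity of each spot was extracted with Agilent Feature Extraction 10.7.1.1, which subtracts background and writes a processed signal. The authors also deposited a table of log2 values, in which each array's values equal the log2 of the processed signal plus a constant of that array (-7.88 to -8.54), within 0.001 for 100% of 39399 probes. The minus log2 75th percentiles of the same arrays were -7.98 to -8.65, and the medians of the table's columns lay between -3.56 and -3.89. The table was used as an alternative only.

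The processed signal of each array was put on the log2 scale and its 75th percentile subtracted. Spots flagged as outliers (98 to 144 per array) were dropped, 0 spots were saturated, and the 10 replicate spots of 399 probes were averaged. Of 39429 probes that were not controls, 30 were left out because every spot was flagged on an array. The lowest signal called well above background lay between 10.1 and 11.6 units, and the median log2 SD of replicate spots between 0.0641 and 0.0725, which sets the precision of a single signal. Probes were named from a table of mouse gene names, 26044 by accession, 3194 by symbol and 930 by synonym, and 9231 kept the array's name. For each of the 31689 genes and unnamed transcripts, the probe with the highest mean signal was used; 6394 had several probes.

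A gene was tested if at least 3 arrays were well above background. The genotype effect was fitted with limma 3.58.1 in R 4.3.3, with age as a factor, so that each age's 2 arrays form a pair. Age effects came from the same fit, and a trend test crossed genotype with the logarithm of age. Adjusted p-values follow Benjamini and Hochberg over all genes tested, with a threshold of 0.05. At a single age, genes well above background on both arrays were counted at 2-fold and 4-fold; where 1 array was below background, the fold is a bound computed from that array's lowest signal called above background, or from the probe's own signal there if that was higher.

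Before the files were opened, 34 gene lists were fixed. They cover surface mucous, gland mucous, chief, parietal, enteroendocrine and intestinal cells, metaplasia markers, Wnt targets, the cell cycle, chemokines, cytokines, growth factors, matrix remodelling, epithelial defence, immune cells, MHC class II, the interferon response, glycosyltransferases, stroma, other tissues, the circadian clock, immediate-early, sex-linked and reference genes. The sex-linked list did not pass (mean -0.03, camera adjusted p = 0.835). Each list was tested over the 3 ages with camera of limma at a preset correlation of 0.01 and with an estimated correlation, and with fry. At each age, a list's median was placed among 10000 random lists matched in 10 bins of expression. Random lists hold unrelated genes, while members of a list can move together. An extreme percentile thus describes 1 mouse against 1 mouse and does not measure the spread between mice. Lists of liver and antrum genes were added after the values were seen.

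Genes were named by a fixed rule. For the genotype effect, genes past the threshold came first, and as none passed, the 12 per direction with the largest moderated t were taken from those with a mean difference of at least 2-fold and the same direction at all ages. At each age these were the 10 largest differences per direction and the 4 largest bounds. For age and trend up to 6 genes that passed were named, and for each list up to 4 members with the largest absolute difference. Some further members (Pgc, Pga5, Muc5ac, Muc6, Lgr5, Tyms, Top2a, Duox2 and others) were named outside the rule, after the values were seen, as known markers of a cell type or as members that went another way. Some genes that the rule would name are not reported here.

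The fit was tested on simulated data with this design and these variances, in 20 runs of 200 changed genes among 17860. It called 0.2% of genes changed 2-fold and 51.8% of those changed 4-fold, and 3.44% of all calls were false. These rates hold for that share of changed genes, which in the real data is not known. A list raised 2-fold was called in 20 of 20 runs with the preset correlation and in 0 with an estimated one. Over all runs, 2 other lists were called. The simulated genes varied independently of each other, while members of real lists were correlated (estimated correlation 0.91 for cell-cycle genes). These runs therefore do not show how often camera calls an unchanged list of correlated genes. At single ages the raised list lay at the 100 percentile in every run, while unchanged reference genes ranged from the 1.8 to the 100 percentile.

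The alternatives were quantile normalization, scaling to the median or to 8 spike-in probes, a normexp background correction with an offset of 50, the authors' value table, no filter on signal, genes above background on all 6 arrays, the mean of a gene's probes, no age term, a variance trend with intensity, other list tests, and each age pair left out. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for loading and figures.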

Results

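RNA from the lining of the mouse stomach was profiled on 6 one-colour Agilent arrays. The tissue was the mucosa of the glandular stomach, taken off the muscle beneath it, from C57BL/6J mice that were either wild type or lacked A4gnt. A4gnt encodes the glycosyltransferase that caps the O-glycans of gland mucin with α1,4-linked N-acetylglucosamine, a sugar carried by the mucus of neck and pyloric gland cells. Mice of 5, 10 and 50 weeks were used, 1 for each genotype and age. Between 54.8% and 59.2% of the 43020 spots on an array that were not controls were well above background, and the 75th percentile of the processed signal lay between 252.8 and 402.8 units. The number of arrays limits the precision. A difference at a single age sets 1 mouse against 1 mouse and has no replicate check, so it carries no p-value. A difference over the 3 ages has 3 arrays per genotype. Its error combines the spread of the 3 within-age differences with a variance estimated over all genes (2 residual and 2.12 prior degrees of freedom).

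The targeted gene was read first. The array's A4gnt probe (NM_001077424; mm9 chromosome 9, 99521093 to 99521152) was well above background on the 3 wild-type arrays, with processed signals of 165, 325 and 264 at 5, 10 and 50 weeks. On the 3 null arrays its signals were 2.30, 2.94 and 2.11, not well above background. A4gnt was therefore at least 15.3-fold lower in the null array at 5 weeks, at least 25.7-fold lower at 10 weeks and at least 36.4-fold lower at 50 weeks. Over the 3 ages A4gnt was at least 24.3-fold lower (limma adjusted p = 0.0922). The labels do not say which part of the gene was removed, so the probe checks the labels only if it lies within that part.

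**Figure D1:**
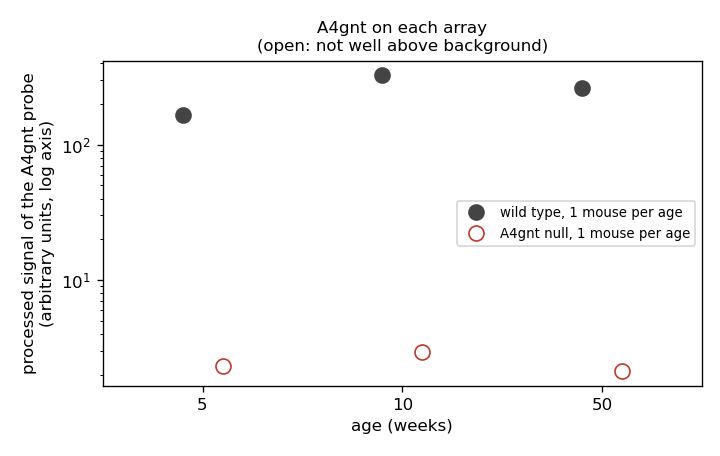
Processed signal of the A4gnt probe (log axis, arbitrary units) on each of the 6 arrays against age in weeks, wild type in grey and A4gnt null in red, 1 mouse per point. The wild-type points sit between 165 and 325, and the null points, drawn open because they were not well above background, between 2.11 and 2.94.

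The comparison of the genotypes over the 3 ages asks what the gastric mucosa expresses differently without the enzyme. As lists, genes of acid-secreting and enzyme-secreting cells were lower in the null arrays, and genes of gland mucous cells, dividing cells, fibroblasts and matrix-degrading enzymes were higher, by camera with its preset correlation. All 6 list calls were lost with an estimated correlation (camera adjusted p = 0.622 with an estimated correlation for each). That test also missed a list raised 2-fold in 20 of 20 simulated runs, so its loss cannot tell a changed list from an unchanged one. By fry, fibroblast genes kept the call (fry adjusted p = 0.0143) and the others lost it (fry adjusted p from 0.130 to 0.224). None of the genes named next passed on its own. The proton pump subunit Atp4a differed by -1.33 ± 0.33 (log2, null minus wild type, ± SE, n = 3 per genotype) and the gland mucin Muc6 by 0.92 ± 0.11. The matrix metalloproteinase Mmp10 was not well above background on any wild-type array and was at least 19.1-fold higher in the null arrays. The DNA topoisomerase Top2a, made in dividing cells, differed by 1.37 ± 0.35.

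No gene passed the per-gene test of genotype. Of 17860 genes and unnamed transcripts tested with limma, 0 were higher and 0 lower at an adjusted p under 0.05. The smallest adjusted p was 0.0922, and 4216 had an unadjusted p under 0.05. A normexp background correction called 97 higher and 92 lower, a variance trend with intensity called 28 and 13, the fit without an age term called 4 and 2, and quantile normalization called 0 and 1. In data simulated with this design, with 200 of 17860 genes changed, the test called 0.2% of genes changed 2-fold and 51.8% of those changed 4-fold. Of the genes changed 2-fold, 90.35% had an unadjusted limma p under 0.05. Rates of adjusted calls depend on the share of genes changed, so these hold for the simulated share only. The slide cannot be told apart from the genotype, because the 3 wild-type arrays shared slide 1 and the 3 null arrays slide 2, each scanned once.

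The genes named here by rank had the largest moderated t among those with a mean difference of at least 2-fold and the same direction at all 3 ages, and did not pass the test. Their limma adjusted p lay between 0.0922 and 0.0967. Bdh2, a hydroxybutyrate dehydrogenase, was 5.54-fold higher in the null arrays (2.47 ± 0.12), and Rgs17, a regulator of G-protein signalling, 5.07-fold higher (2.34 ± 0.12). Ceacam2, an adhesion molecule, was 5.07-fold higher and Mcpt2, a protease of mucosal mast cells, 3.63-fold higher. Rnf183, a ubiquitin ligase, was at least 5.49-fold higher, and Clec7a, the beta-glucan receptor of myeloid cells, at least 6.13-fold. Ccl7, a chemokine that attracts monocytes, was at least 2.11-fold higher, and the Tudor-domain gene Tdrd12 at least 1.99-fold. Wild-type signals of Rnf183, Clec7a, Ccl7 and Tdrd12 were not well above background on any array, so their ranks and adjusted p rest on such signals. Those of the next 4 genes were not well above background on some arrays, so their ranks rest on such signals in part. The neurturin receptor gene Gfra2 was at least 5.21-fold higher at 5 weeks, Prss12 at least 4.90-fold at 5 weeks, Ccdc151 at least 5.78-fold at 50 weeks, and the acid phosphatase gene Acpp at least 22.1-fold at 5 weeks and at least 12.6-fold at 50 weeks.

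Among the lower genes, Egf, the epidermal growth factor precursor, was 4.87-fold lower in the null arrays (-2.28 ± 0.17). Dmbx1, a homeobox gene, was 5.09-fold lower, and Pxylp1, which encodes a phosphatase acting on proteoglycan linkage sugars, 4.79-fold lower. Pxylp1 lies within 20 Mb of A4gnt on chromosome 9. Cdkl1, a kinase gene, was 3.61-fold lower, the pseudogene Speer8-ps1 3.42-fold, Sectm1b 3.45-fold and Atp13a4 3.46-fold. Wipf3 was 3.04-fold lower, and Myo7a, an unconventional myosin, 2.66-fold. Irf7, a transcription factor of the interferon response, differed by -1.73 at 5 weeks and -1.78 at 10 weeks and was at least 2.59-fold lower at 50 weeks. Ccdc154 was at least 3.37-fold lower at 10 weeks and differed by -1.79 at 50 weeks. Rimkla was not well above background on any null array and was at least 2.68-fold lower there. Of all genes above background on all 6 arrays, 71 were at least 2-fold higher and 82 at least 2-fold lower in the null array at all 3 ages. With normexp the balance turned, to 41 higher and 24 lower, and among genes under 2-fold apart between wild-type arrays it was 21 and 33.

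Genes of the gastric gland divided by cell type. All 12 parietal cell genes were lower in the null array at all 3 ages, and 11 were lower when adjusted over the list alone, against 0 over all genes tested. Their mean difference was -1.08 (camera adjusted p = 4.98e-07; adjusted p = 0.622 with an estimated correlation). The anion exchanger Slc26a7 differed by -1.75 ± 0.37 and the potassium channel Kcnj15 by -1.26 ± 0.16. The histamine receptor Hrh2, not well above background on the null arrays of 10 and 50 weeks, was at least 2.48-fold and at least 2.33-fold lower there. Of 8 chief cell genes tested, 7 were lower at all 3 ages and 5 were lower when adjusted over the list alone, again against 0 over all genes. Their mean difference was -0.98 (camera adjusted p = 0.00473; adjusted p = 0.622 with an estimated correlation). Without the 50-week pair the chief cell mean was -0.64. The intrinsic factor gene Cblif differed by -0.22, -1.43 and -1.34 at 5, 10 and 50 weeks, the protein disulfide isomerase gene Pdia2 by -1.23 ± 0.29 and Bhlha15, a transcription factor of secretory cells, by -1.11 ± 0.12. Cpb1, a carboxypeptidase also made by the pancreas, differed by -0.61 at 5 weeks and -6.06 at 50 weeks. The pepsinogen genes went apart, with Pgc at -0.85 ± 0.20 and Pga5 at 0.40 ± 0.27. On the same arrays a list of antrum genes, added after the values were seen, stood at 1.81, 1.61 and 0.59 at 5, 10 and 50 weeks.

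Gland mucous cell genes were higher by 0.79 on average, 7 of 9 at all 3 ages and 5 when adjusted over the list alone (0 over all genes). The camera adjusted p was 8.18e-04, with an adjusted p of 0.622 with an estimated correlation. Gkn3, made by pyloric gland and neck cells, differed by 1.85 ± 0.18, the water channel Aqp5 by 1.77 ± 0.37 and Glipr1 by 0.52 at 10 weeks and 1.09 at 50 weeks. Surface mucous cell genes differed by -0.24 on average and did not pass (camera adjusted p = 0.0804), though they did under quantile normalization (camera adjusted p = 0.00936). The surface mucin Muc5ac stood at -0.34 ± 0.15 and Psca at -0.70 ± 0.22. Enteroendocrine genes were lower by -0.52 on average (camera adjusted p = 0.0432; adjusted p = 0.647 with an estimated correlation), with 0 of 13 passing when adjusted over the list alone. That call was lost without the 50-week pair (mean -0.15, camera adjusted p = 0.460), without the 10-week pair (0.0719), with the mean of a gene's probes (0.0756) and without an age term (0.0602). Without the 5-week pair the enteroendocrine mean was -0.97. Gastrin, Gast, made by antral G cells, differed by 1.77 at 5 weeks, -1.20 at 10 weeks and -5.03 at 50 weeks.

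Markers of metaplasia were higher by 0.89 on average in the null arrays, 7 of 10 at all 3 ages and 5 when adjusted over the list alone (0 over all genes; camera adjusted p = 8.22e-04). The adjusted p was 0.622 with an estimated correlation. The hyaluronan receptor Cd44 differed by 1.75 ± 0.15, the membrane mucin Muc4 by 1.85 ± 0.23 and Dmbt1, a secreted scavenger receptor protein, by 1.79 ± 0.22. The chloride channel Cftr differed by 2.18 ± 0.74. Other markers did not rise, and 1 of the 10 was lower at all 3 ages. Wfdc2 differed by -0.22, -0.06 and -0.03 at 5, 10 and 50 weeks. Olfm4 was at least 4.89-fold lower at 5 weeks and at least 1.15-fold higher at 50 weeks. Intestinal cell genes gave no common direction over the ages (mean 0.20, camera adjusted p = 0.763), with means of -0.03 without the 5-week pair and 0.65 without the 50-week pair. When adjusted over the list alone, 3 were higher, among them Gpa33 (1.38 ± 0.20), and 3 lower, among them the apolipoprotein Apoa4 (-1.55 ± 0.43). Stem cell and Wnt target genes differed by 0.02 on average (camera adjusted p = 0.988), with the stem cell receptor Lgr5 at -0.13 ± 0.16.

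Cell-cycle genes were higher by 1.01 on average, with 22 of 23 higher at all 3 ages and 15 when adjusted over the list alone (0 over all genes). The camera adjusted p was 8.57e-08, and the adjusted p was 0.622 with an estimated correlation. Without the 10-week pair the cell-cycle mean was 0.61. The survivin gene Birc5 differed by 1.42 ± 0.39, the cyclin Ccnb1 by 1.37 ± 0.40 and the ubiquitin-conjugating enzyme Ube2c by 1.37 ± 0.37. Tyms, the thymidylate synthase, differed by -0.05 ± 0.20. Fibroblast genes were higher by 0.63 on average, with 8 of 12 passing when adjusted over the list alone (0 over all genes; camera adjusted p = 6.75e-05; adjusted p = 0.622 with an estimated correlation). The growth factor receptor Pdgfra differed by 1.03 ± 0.24 and the intermediate filament gene Vim by 0.97 ± 0.17. Matrix remodelling genes were higher by 2.11 on average, 10 of 14 when adjusted over the list alone (0 over all genes; camera adjusted p = 2.43e-07; adjusted p = 0.622 with an estimated correlation). The collagenase Mmp13 was at least 6.64-fold higher. The stromelysin Mmp3 was at least 7.43-fold higher at 5 weeks and at least 23.5-fold higher at 50 weeks, where the wild-type array was not well above background, and differed by 2.78 at 10 weeks. With normexp the mean of the matrix list was 0.84, and it was also smaller than the main value with genes above background on all 6 arrays (camera adjusted p = 0.00160).

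**Figure D2:**
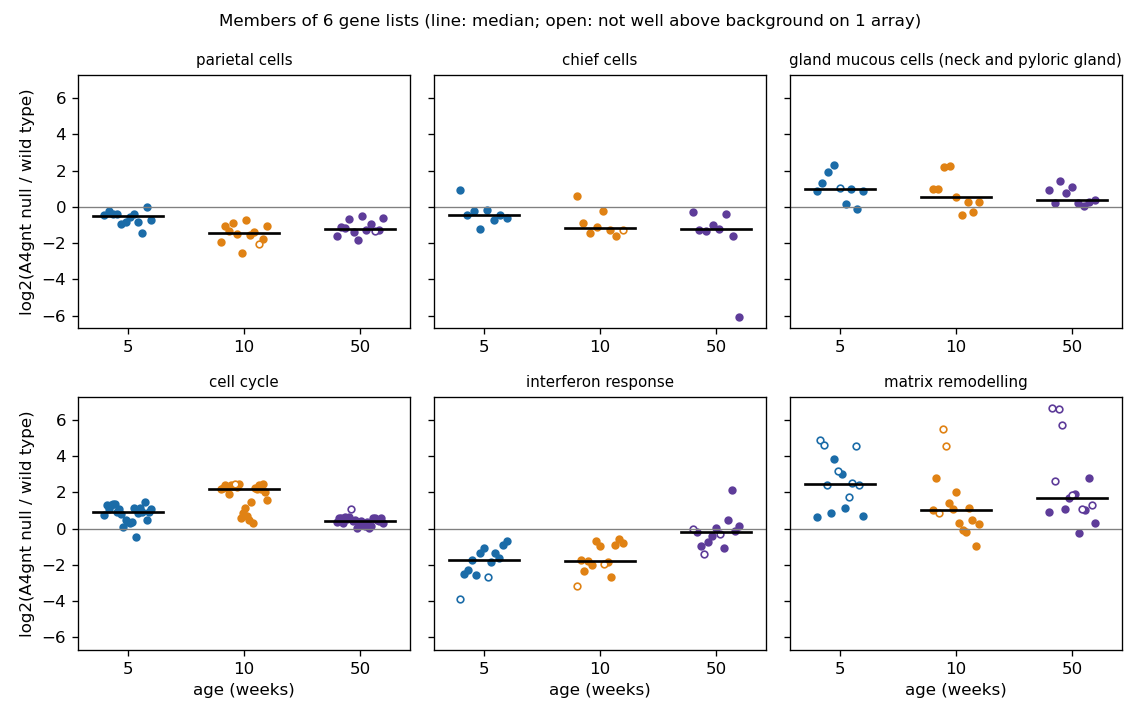
Difference between the A4gnt-null and wild-type arrays (log2) of each measured member of 6 gene lists against age in weeks, 1 mouse of each genotype per age; lines mark medians, and open points were not well above background on 1 of the 2 arrays. Parietal cell medians were -0.51, -1.44 and -1.21 at 5, 10 and 50 weeks, and cell-cycle medians 0.93, 2.20 and 0.41.

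Inflammatory genes were higher in the null arrays in part. Chemokine ligands were higher by 0.89 on average, 8 of 22 when adjusted over the list alone (0 over all genes; camera adjusted p = 0.00291; adjusted p = 0.622 with an estimated correlation). Cxcl5, which attracts neutrophils, was at least 6.19-fold higher, and Cxcl1 and the monocyte attractant Ccl2, not well above background on the wild-type arrays of 5 and 50 weeks, were at least 12.5-fold and at least 6.01-fold higher at 50 weeks. Restricted to genes above background on all 6 arrays, the call was lost (mean 0.24, camera adjusted p = 0.310), and with normexp the mean was 0.21. Cytokine genes did not pass (mean 1.01, camera adjusted p = 0.237). Their mean was 0.62 with normexp and 0.32 without a filter on signal. Of the 6 tested, 2 were higher when adjusted over the list alone, namely Il11 and Il1b. Il11, a cytokine acting on epithelium and stroma, differed by 3.01 ± 0.60. Il1b was not well above background on the wild-type array of 50 weeks and was at least 15.6-fold higher in the null array of that age. Growth factors did not pass (camera adjusted p = 0.249), but did without a filter on signal (camera adjusted p = 0.0274). Their mean was 0.43 (0.21 with normexp) and their median -0.01, with 6 higher and 2 lower when adjusted over the list alone. Hgf, the hepatocyte growth factor, was at least 3.06-fold higher, and neuregulin Nrg1 and keratinocyte growth factor Fgf7 differed by 2.49 ± 0.20 and 2.07 ± 0.30. Fgf18 was lower (-0.96 ± 0.12). The study is known to have picked some chemokine, cytokine and growth factor genes on these mice. Counts over these lists alone, and their camera results, are therefore not independent evidence.

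Macrophage genes were higher by 0.44 on average, 2 of 11 when adjusted over the list alone (0 over all genes; camera adjusted p = 0.00291; adjusted p = 0.622 with an estimated correlation). These were Mpeg1, a pore-forming protein of macrophages (0.93 ± 0.16), and Aif1 (0.86 ± 0.18). At all 3 ages 6 of the 11 were higher and 0 lower. Csf1r differed by 0.31, -0.10 and 0.21 at 5, 10 and 50 weeks, and Itgam by -0.14, 0.10 and -0.22. Cd163 was at least 4.64-fold lower in the null array at 5 weeks. With normexp the macrophage mean was 0.20 (camera adjusted p = 0.0449), and without a filter on signal 0.26. Antigen-presenting MHC class II genes were higher by 0.57 on average, 4 of 6 when adjusted over the list alone (0 over all genes; camera adjusted p = 0.0364; adjusted p = 0.622 with an estimated correlation), H2-Ab1 among them (1.03 ± 0.20). Without the 10-week pair the MHC class II call was lost (camera adjusted p = 0.0605), and so it was without the 50-week pair (0.0512) and without an age term (0.0602). Epithelial defence genes were higher by 1.5 on average, 2 of 14 when adjusted over the list alone (0 over all genes; camera adjusted p = 0.0227; adjusted p = 0.622 with an estimated correlation). These were the C-type lectin Reg3g (4.43 ± 0.50) and the siderophore-binding Lcn2 (2.18 ± 0.36), and Duox2, an epithelial oxidase, stood at -1.16 ± 0.36. That call was lost without the 10-week pair (camera adjusted p = 0.0605).

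Genes of the interferon response were lower by -1.23 on average in the null arrays, 4 of 13 when adjusted over the list alone (0 over all genes). The camera adjusted p was 5.00e-05, and the adjusted p was 0.622 with an estimated correlation. The ubiquitin-like modifier Isg15 differed by -1.85 ± 0.32, Oasl2 by -1.76 ± 0.40 and the deconjugating protease Usp18 by -1.59 ± 0.21. The antiviral gene Ifit1, not well above background on the null arrays of 5 and 10 weeks, was at least 5.33-fold and at least 2.17-fold lower there. List medians were -1.73 at 5 weeks and -1.78 at 10 weeks, each below all 10000 random lists matched on expression. At 50 weeks the median was -0.21, at the 14.4 percentile. Here and below, such percentiles take no account of members that move together or of the spread between mice. With normexp the mean was -0.66 and the medians at 5 and 10 weeks -0.78 and -0.46.

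Of the immune, glycosylation, stromal and control lists that remain, only the circadian clock passed. Neutrophil genes differed by 0.66 on average (camera adjusted p = 0.0943) and passed without the 10-week pair (camera adjusted p = 0.00737) and without a filter on signal (camera adjusted p = 9.82e-06). With normexp the neutrophil mean was 0.25 (camera adjusted p = 0.410), and without the 5-week pair 0.35. Mast cell genes differed by 0.62 (0.23 without a filter on signal; camera adjusted p = 0.217), with 3 of 6 higher and 1 lower when adjusted over the list alone; the proteases Mcpt2 (1.86 ± 0.14) and Mcpt4 (1.66 ± 0.25) were higher and the receptor Kit lower (-0.87 ± 0.16). T cell genes had a mean of -0.24 (0.18 with genes above background on all 6 arrays) and a median of 0.03 (camera adjusted p = 0.835), and B and plasma cell genes a mean of 0.49 (0.10 with normexp; camera adjusted p = 0.303). Glycosyltransferases of mucin O-glycans differed by 0.07 on average (camera adjusted p = 0.363), with the sialyltransferase St3gal4 at 1.25 at 10 weeks and 1.61 at 50 weeks and the fucosyltransferase Fut4 at -0.91 ± 0.13. Endothelial genes (0.16, camera adjusted p = 0.584), enteric neuron and glia genes (0.49, camera adjusted p = 0.479) and reference genes (0.16, camera adjusted p = 0.127) did not pass either. With normexp the endothelial mean was -0.02, and without the 5-week pair the enteric mean was 0.02. Enteric genes did pass without the 50-week pair (camera adjusted p = 0.0409), and reference genes did with normexp (camera adjusted p = 0.0449) and without a filter on signal (camera adjusted p = 0.0265). Circadian clock genes were lower by -0.37 on average (camera adjusted p = 0.0468, and 0.622 with an estimated correlation). Their mean was -0.23 with normexp, and 0 of 15 passed when adjusted over the list alone. By fry the circadian list did pass (fry adjusted p = 0.0143). The circadian call was lost without the 5-week or the 50-week pair (camera adjusted p = 0.0910 and 0.0566), under quantile normalization (0.0846), without a filter on signal (0.0722), with genes above background on all 6 arrays (0.165), with the mean of a gene's probes (0.0968) and without an age term (0.134).

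Markers of tissue from outside the glandular mucosa also differed between the arrays. Pancreatic acinar genes were lower by -1.45 on average in the null arrays (camera adjusted p = 0.0432; adjusted p = 0.736 with an estimated correlation), 2 of 13 when adjusted over the list alone (0 over all genes), among them the trypsinogen Prss2 (-2.54 ± 0.44). That call was lost without the 50-week pair (mean -0.50, camera adjusted p = 0.119), with genes above background on all 6 arrays (mean -0.96, camera adjusted p = 0.134) and without an age term (0.354). Squamous forestomach genes had a mean of -0.38 and a median of 0.07 over the 7 members tested (camera adjusted p = 0.941); without a filter on signal the mean was -1.63 (camera adjusted p = 0.0274). The filter leaves out Krtdap and other members seen on few arrays. Among genes of the muscle layer, smooth muscle genes had a mean of -0.04 and a median of 0.04 (camera adjusted p = 0.988). Leaving out the 50-week pair turned the smooth muscle mean to 0.98 (camera adjusted p = 8.03e-04), and leaving out the 5-week pair made it -0.91. Adipocyte genes differed by -0.74 (camera adjusted p = 0.565), erythroid genes by 0.81 (camera adjusted p = 0.231) and immediate-early genes by 0.32 (camera adjusted p = 0.217). Erythroid genes passed without the 50-week pair (1.39, camera adjusted p = 0.0409), and immediate-early genes without the 10-week pair (0.77, camera adjusted p = 5.94e-05) and without a filter on signal (camera adjusted p = 0.0274). Without the 5-week pair the erythroid, immediate-early, adipocyte and forestomach means were -0.11, -0.03, -1.32 and -1.24. Leaving out the 10-week pair instead gave adipocyte and forestomach means of -0.23 and 0.01, and leaving out the 50-week pair a forestomach mean of 0.10.

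**Figure D3:**
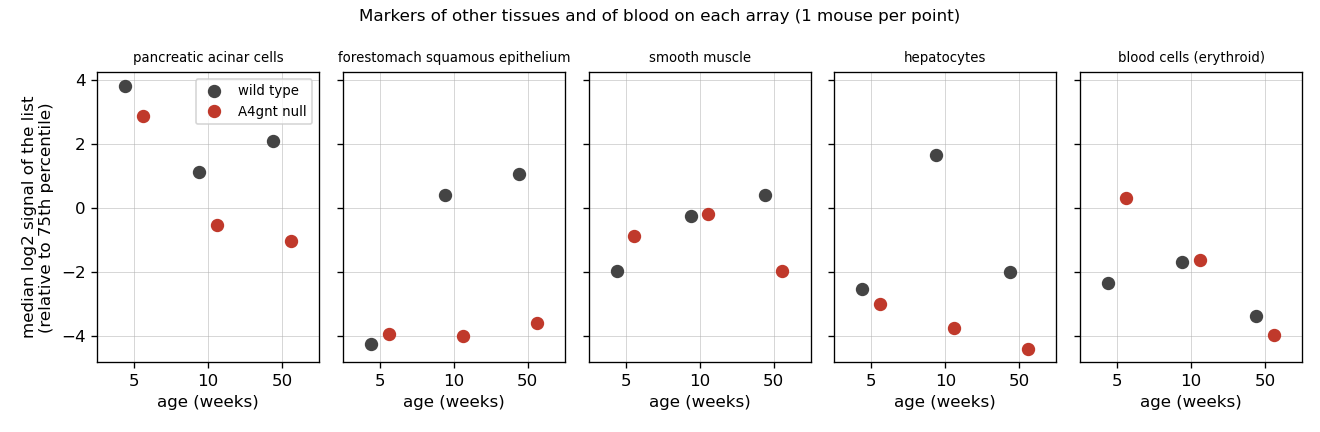
Median normalized log2 signal of genes of pancreatic acini, squamous forestomach, smooth muscle, liver and erythroid cells on each of the 6 arrays against age in weeks, wild type in grey and A4gnt null in red, 1 mouse per point. Forestomach genes stood at 0.40 and 1.08 on the wild-type arrays of 10 and 50 weeks and between -3.58 and -4.25 on the other 4 arrays.

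At 5 weeks, the null array had higher levels of neutrophil, matrix remodelling and dividing-cell genes than the wild-type array, and lower levels of interferon response genes. S100a8, a calcium-binding protein of neutrophils, was 20.3-fold higher, and Timp1, an inhibitor of metalloproteinases, 14.5-fold higher. Reg3g was 15.3-fold higher, and F3, the tissue factor that starts clotting, 13.6-fold higher. Oas2, an antiviral oligoadenylate synthetase, was 9.91-fold lower, and Ifit3 5.63-fold lower. Of 16394 genes measured on both arrays, 582 were at least 2-fold higher and 795 at least 2-fold lower in the null array, and 111 and 56 at least 4-fold. With the normexp background correction the balance turned, to 293 higher and 244 lower. Among genes under 2-fold apart between wild-type arrays, a filter added after the values were seen, 13 and 8 were at least 4-fold apart. A further 263 and 284 genes had a bound of at least 2-fold. For scale, 1187 genes were at least 2-fold apart between the wild-type mice of 5 and 10 weeks, which also differed in sex-linked genes.

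The highest differences at 5 weeks also included the whey acidic protein family gene Wfdc18 (33.0-fold), Prap1 (18.8-fold), the annexin Anxa8 (17.6-fold), the cornified-envelope gene Sprr2g (17.0-fold), Carmil3 (16.9-fold) and the retinaldehyde dehydrogenase Aldh1a3 (15.8-fold). The lowest included the apolipoprotein Apob (8.28-fold), the pancreatic protease Ctrl (7.92-fold), Ptprd (6.08-fold), Oasl2 (5.94-fold), Pou3f1 (5.94-fold), Mir205hg (5.64-fold), Pxylp1 (5.61-fold) and Kcnq1ot1 (4.95-fold). Second probes gave smaller log2 differences for Anxa8 (1.09 against 4.14) and Ptprd (-1.22 against -2.60). The growth factor epiregulin, Ereg, was at least 34.8-fold higher in the null array, Acpp at least 22.1-fold, Catsperb at least 21.8-fold and the claudin Cldn2 at least 20.6-fold. The cytokine oncostatin M, Osm, was at least 19.7-fold lower, Pcdh17 at least 17.4-fold, Cd109 at least 16.3-fold and Retnla, a product of alternatively activated macrophages, at least 15.8-fold.

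Of the lists at 5 weeks, the medians of matrix remodelling (2.48), neutrophil (1.43), cell-cycle (0.93), gland mucous (0.97) and fibroblast genes (0.82) lay above all 10000 random lists. With members below background set at their bound, the matrix median was 1.18 and the neutrophil median 0.63. Parietal and chief cell medians were -0.51 (0.02 percentile) and -0.45 (0.24 percentile). Mast cell genes had a median of 1.22 (99.99 percentile), chemokines 0.59 (99.99), macrophages 0.39 (98.99) and epithelial defence genes 0.27 (97.79). On the same pair of arrays, smooth muscle genes were higher (median 1.74), as were erythroid genes (2.44) and immediate-early genes (1.12), and pancreatic genes were lower (-1.29). With normexp the matrix, neutrophil, fibroblast, mast cell and smooth muscle medians were 0.51, 0.26, 0.43, 0.61 and 0.75, and those of chemokines, macrophages and epithelial defence 0.24, 0.25 and 0.08. Scaling to the spike-in probes moved the median of all genes by 0.15 at 5 weeks, -0.12 at 10 weeks and -0.06 at 50 weeks.

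At 10 weeks, genes of epithelial defence and of dividing cells stood higher in the null array, and liver genes and acid-secreting cell genes lower. Reg3b, an antibacterial lectin, was 61.8-fold higher, and Saa3, an acute-phase protein, 55.8-fold higher. Il1rl1, the interleukin 33 receptor, was 17.6-fold higher, and Alpi, the intestinal alkaline phosphatase, 16.6-fold higher. Of 17118 genes measured on both arrays, 735 were at least 2-fold higher and 901 at least 2-fold lower in the null array, and 169 and 160 at least 4-fold. With normexp these were 359 and 485, and 61 and 76, and among genes under 2-fold apart between wild-type arrays 25 and 18 were 4-fold apart. A further 242 and 339 genes had a bound of at least 2-fold. Between the wild-type mice of 10 and 50 weeks, 1049 genes were at least 2-fold apart.

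The highest differences at 10 weeks also included Wfdc18 (219-fold), Prap1 (60.8-fold), the tryptase Prss28 (21.4-fold), the pentraxin Nptx2 (14.9-fold), Acpp (13.3-fold) and Cnot9 (12.5-fold). The 10 lowest were mostly liver products. They were Serpina1e (95.4-fold), Serpina1a (88.1-fold) and Serpina1c (85.6-fold), which encode protease inhibitors of plasma, Bhmt (89.8-fold), albumin, Alb (80.6-fold), Apoc3 (48.4-fold), Cyp4a10 (37.0-fold), Cyp4a31 (36.7-fold), fetuin, Ahsg (33.5-fold) and Slc27a2 (28.8-fold). Second probes gave smaller log2 differences for Il1rl1 (1.78 against 4.13), Serpina1e (-5.57 against -6.58) and Serpina1a (-5.07 against -6.46). Kctd18 was at least 53.8-fold higher in the null array, Rpl10l at least 51.3-fold, Ntng1 at least 33.3-fold and Fgf12 at least 30.7-fold. Cyp4a14 was at least 267-fold lower, Igfbp1 at least 188-fold, the alcohol-oxidizing Cyp2e1 at least 115-fold and Serpina3k at least 104-fold.

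Cell-cycle genes had a median of 2.20 at 10 weeks, matrix remodelling genes 1.04, metaplasia markers 0.89 and epithelial defence genes 1.48, each above all 10000 random lists. With members below background at their bound, the defence median was 0.85. MHC class II genes stood at 1.13 (99.99 percentile), intestinal genes at 0.77 (99.99) and fibroblast genes at 0.54 (99.98). The intestinal transcription factor Cdx2 was well above background only on the null array, and was at least 9.65-fold higher there. Parietal, chief and enteroendocrine medians were -1.44, -1.18 and -0.98, each below all 10000 random lists. On the same arrays, forestomach genes stood at -3.18 (-1.54 with members below background at their bound) and a list of liver genes, added after the values were seen, at -4.95. Immediate-early genes stood at -0.51 (0.11 percentile). With normexp the matrix, defence, intestinal, enteroendocrine and forestomach medians were 0.56, 0.73, 0.47, -0.47 and -0.58.

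At 50 weeks, epithelial defence and matrix remodelling genes were higher in the null array, and pancreatic, squamous, smooth muscle and acid-secreting cell genes lower. Reg3b was 96.7-fold higher, Saa3 63.9-fold, Reg3g 55.9-fold and the iron-binding protein lactoferrin, Ltf, 28.9-fold. Il11 was 20.6-fold higher. The stromelysin genes Mmp10 and Mmp3 were at least 41.7-fold and at least 23.5-fold higher. Of 17074 genes measured on both arrays, 341 were at least 2-fold higher and 737 at least 2-fold lower in the null array, and 53 and 116 at least 4-fold. With normexp these were 183 and 303, and 21 and 50, and among genes under 2-fold apart between wild-type arrays 14 and 15 were 4-fold apart. A further 102 and 300 genes had a bound of at least 2-fold. Between the wild-type mice of 5 and 50 weeks, which also differed in sex-linked genes, 1287 genes were at least 2-fold apart.

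The highest differences at 50 weeks also included Reg1 (27.0-fold), Il1rl1 (16.5-fold), Wfdc18 (13.2-fold), the acute-phase glycoprotein Lrg1 (11.8-fold) and the membrane mucin Muc13 (9.16-fold). The lowest were digestive enzymes of the pancreas, namely Cela3a (138-fold), Cpa1 (112-fold), Cela3b (79.8-fold), Cpb1 (66.7-fold), Pnlip (61.6-fold) and Ctrb1 (28.6-fold), with the cornified-layer genes Lor (113-fold) and Cnfn (40.3-fold) and gastrin, Gast (32.6-fold). Second probes gave smaller log2 differences for Il1rl1 (1.78 against 4.05) and Cela3a (-5.24 against -7.11). Follistatin, Fst, was at least 49.6-fold higher in the null array and Clec2f at least 21.1-fold. The squamous genes Lce3b, Lce3a, Krtdap and Crct1 were at least 96.5-, 92.8-, 87.2- and 86.6-fold lower.

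Matrix remodelling (1.68), epithelial defence (1.54), metaplasia (0.72), fibroblast (0.66), neutrophil (0.68) and cell-cycle medians (0.41) at 50 weeks lay above all 10000 random lists. With members below background at their bound, the matrix median was 1.09 and the neutrophil median 0.28. Parietal and chief cell medians were -1.21 and -1.25, and intestinal and enteroendocrine medians -1.29 and -0.96, each below all random lists. Chemokine genes had a median of 0.55, cytokines 1.17 and mast cell genes 0.49, and with the normexp background correction these stood at -0.02, -0.14 and -0.12. With members below background at their bound, the chemokine median was 0.19 and the cytokine median 0. On the same arrays, pancreatic genes stood at -3.28, forestomach genes at -3.82 (-2.90 with members below background at their bound), smooth muscle genes at -2.46 and adipocyte genes at -2.31 (-1.56 with bounds). With normexp, intestinal, forestomach, smooth muscle and adipocyte medians were -0.86, -1.08, -1.59 and -0.68, and those of matrix remodelling and neutrophil genes 0.30 and 0.01.

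**Figure D4:**
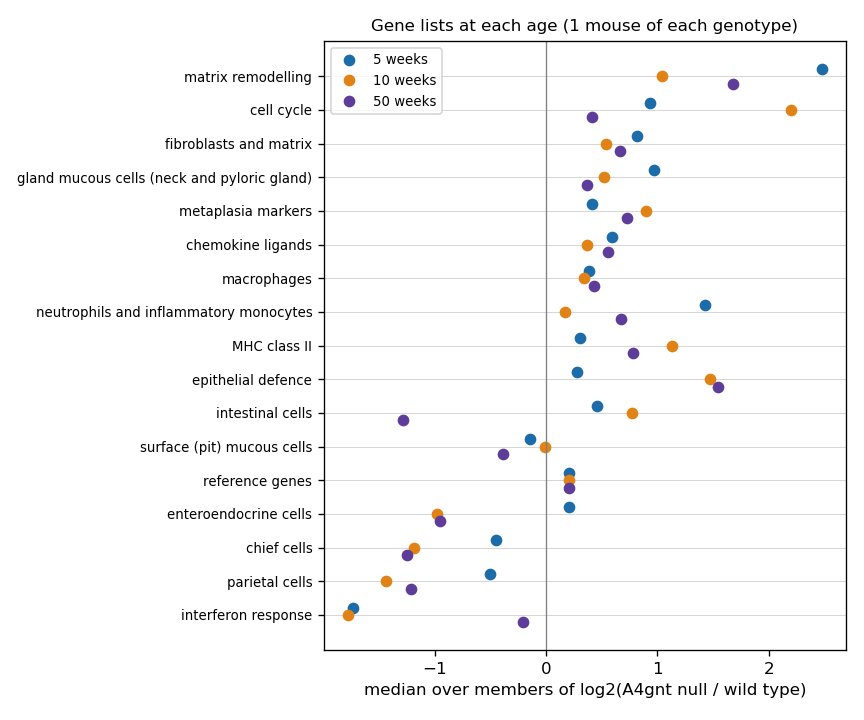
Median difference between the A4gnt-null and wild-type arrays (log2) of 17 gene lists at 5, 10 and 50 weeks, 1 mouse of each genotype per age. Matrix remodelling medians were 2.48, 1.04 and 1.68, and reference gene medians 0.21, 0.21 and 0.20.

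The genotype difference was compared between ages across the 15968 genes above background on all 6 arrays. Genes are not independent replicates, so these values describe the arrays. The differences at 10 and 50 weeks correlated most (Pearson r = 0.66, Spearman rho = 0.62), and 516 of the 529 genes at least 2-fold apart at both ages went the same way. For 5 and 10 weeks r was 0.37 (rho 0.39; 322 of 379 genes), and for 5 and 50 weeks 0.40 (rho 0.46; 242 of 325 genes). Parietal cell genes such as Atp4a went from -0.45 at 5 weeks to -1.91 and -1.63, and the defence gene Reg1 from -0.27 to 3.53 and 4.76. The 5-week pair also differed from the older pairs in sex-linked genes, so these changes cannot be laid to age alone. No gene passed a limma test for a steady trend of the genotype difference with the logarithm of age (0 at an adjusted p under 0.05, smallest 0.9996; 620 at an unadjusted p under 0.05).

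The effect of age was fitted over both genotypes. Eif2s3y and Ddx3y, which are carried on the Y chromosome, were higher at 50 than at 5 weeks (limma adjusted p = 0.0110 and 0.0162). They were also higher at 10 than at 5 weeks (limma adjusted p = 0.0137 for both). Neither was well above background on a 5-week array, so the difference is a bound. Eif2s3y was at least 58.2-fold higher at 50 weeks and at least 43.7-fold at 10 weeks, and Ddx3y at least 15.2-fold and at least 18.0-fold. Xist, made from the inactive X chromosome of females, was well above background on the 5-week arrays alone, with log2 signals of -0.67 in the wild type and -1.92 in the null. The Y-linked Kdm5d and Uty were also below background at 5 weeks and did not pass between 5 and 50 weeks (limma adjusted p = 0.145 and 0.217). This is the pattern of female mice at 5 weeks and male mice at 10 and 50 weeks. Sex therefore cannot be told apart from age in any comparison of 5 weeks with an older age. No gene fell at 0.05, and 3413 and 2170 genes had an unadjusted p under 0.05 for 50 and 10 against 5 weeks. Normexp called 4 genes lower for 50 and 2 for 10 against 5 weeks, and without a filter on signal 0 genes were called higher. With genes above background on all 6 arrays, 0 were called higher too. That filter leaves out Eif2s3y and Ddx3y, so it could not have called them. A contrast of 50 against 10 weeks, added after the values were seen, called 0 genes (1223 at an unadjusted p under 0.05; limma, smallest adjusted p = 0.710).

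Within each genotype, ages were compared by fold alone. Sex-linked genes differed between 5 weeks and the older ages, so counts against 5 weeks mix sex with age. In the wild type, 1187 genes were at least 2-fold apart between 5 and 10 weeks, 1287 between 5 and 50 weeks and 1049 between 10 and 50 weeks. In the null mice the counts were 951, 1608 and 538. The age differences of the wild-type and null mice correlated across genes with r = 0.14 for 10 against 5 weeks, 0.47 for 50 against 5 weeks and 0.40 for 50 against 10 weeks. Gene groups moved apart in the same comparison. The median signal of the parietal cell list was 3.93, 3.52 and 3.11 in the wild type at 5, 10 and 50 weeks and 3.18, 2.17 and 1.99 in the null, while that of cell-cycle genes was -0.25, -0.02 and 1.55 in the wild type and 0.61, 2.14 and 2.10 in the null.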

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

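Some gene groups went opposite ways at 2 ages, which flagged them; with 1 mouse per group the differences between ages were not tested. Intestinal cell genes had a median difference of 0.77 at 10 weeks and -1.29 at 50 weeks. Smooth muscle genes stood at 1.74 at 5 weeks and -2.46 at 50 weeks, forestomach genes at 0.70 at 5 weeks and -3.82 at 50 weeks, and immediate-early genes at 1.12 at 5 weeks and -0.51 at 10 weeks. With normexp the intestinal medians were 0.47 and -0.86 and the forestomach medians 0.30 and -1.08.

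The tests of antrum, of dilution and of tissue from outside the mucosa were chosen only after the result was seen. Parietal and chief cell genes were lower in the null arrays while antrum genes were higher, by a median of 0.589 at 50 weeks and 1.61 at 10 weeks, so more antrum in the null pieces could account for part of the loss. Against this, the antrum median was highest at 5 weeks (1.81), where the parietal median was only -0.51. Gast and Sst, also antral, were lower at 10 and 50 weeks, and Gkn3 and Aqp5 belong to the gland mucous list too. The 6 antrum genes hardly moved together over the arrays (mean correlation 0.126), so the list is a weak measure of antrum content. Its median signal at 10 and 50 weeks was 3.50 and 3.45 in the wild type and 3.49 and 3.315 in the null. Plain dilution by other tissue would lower all gland genes alike, but gland mucous genes stood 1.82 above parietal and chief genes. The lists had already been seen to go apart, so the permutation p of 6e-05, over genes that are not independent, adds little. Dilution would also raise markers of outside tissue in the null arrays. At 10 and 50 weeks, liver medians were -4.95 and -2.97 and forestomach medians -3.18 and -3.82. Those of pancreas were 0.02 and -3.28, and of smooth muscle 0.29 and -2.46. A loss of acid-secreting cells with growth of mucous gland cells in mice without the enzyme could act as well, and the arrays do not separate it from the choice of region.

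The test of outside tissue was chosen only after the result was seen. Members of the lists for pancreas, liver, forestomach and smooth muscle moved together across the 6 arrays with mean correlations of 0.559, 0.793, 0.397 and 0.837. The lowest, 0.397, leaves open whether pieces of other tissue may explain every one of these lists. It was that of forestomach genes, many of which were near background on most arrays, so it cannot decide for that list. On the wild-type arrays of 10 and 50 weeks, 12 and 13 of 13 forestomach members were well above background, against 6 or 7 on each other array. Those wild-type pieces could hold some forestomach. The wild-type 10-week array, where liver genes had a median signal of 1.66, above the other 5, could hold some liver.

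The tests of DNA around the locus were chosen only after the result was seen; those of splits, probes and slides were set before. Among genes at least 2-fold apart the same way at all 3 ages, a second probe went the same way for 87.5% (14 of 16; exact binomial 95% interval 61.7 to 98.4%), so single faulty probes are not a likely source of most. Because 0 slides held both genotypes, labelling or scan differences could act on whole transcripts unseen. Of these genes 1.96% lay within 20 Mb of A4gnt (Bcl2a1d, Rbp2 and Pxylp1), against 1.69% of all genes measured (Fisher's exact test, p = 0.746). DNA carried along with the targeted locus could be a local source of those 3, but most lie elsewhere. Their position does not test an effect of that DNA on distant genes. The 6 arrays have 10 splits into 3 and 3, too few for a share under 0.05. Counting the real split, 10 gave at least as many adjusted calls as it did (0, highest other 0). With 0 real calls that outcome was fixed, so it shows nothing. For genes at an unadjusted p under 0.05, only the real split gave as many (4216, highest other 1392). For lists 3 did, the real one among them (15, highest other 18). The splits with 1392 genes or 18 lists part a single age pair. The 3 others that part all 3 pairs gave 208 to 513 such genes and called 8 to 12 lists.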

How the results depend on the processing

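The alternatives were listed before the data were examined, except the scaling to spike-in probes and the filter on wild-type spread. Where a result moved, the cause was not tested. Of the main results, which are counts, 178 stayed and 60 moved. Of the others 1566 stayed, 47 lost and 49 gained a call, 218 moved and 10 turned direction. Among those added 2 and 29 stayed and 14 moved. A result was said to turn direction only if it was called, or at a single age reached 2-fold or an extreme percentile. Other sign changes counted as moved, among them all 18 list means and 4 genes over the 3 ages that moved. Results called under neither setting counted as stayed if their sign held. Quantile normalization called 1 gene lower for genotype. With normexp, genotype calls were 97 and 92, age calls 9 and 4 for 50 against 5 weeks and 2 lower for 10 against 5; genes 2-fold higher and lower were 293 and 244, 359 and 485, and 183 and 303 at 5, 10 and 50 weeks, 4-fold 43 and 13, 61 and 76, and 21 and 50, and at all ages 41 and 24. Age pairs differed at 432, 489 and 445 genes in the wild type and 383, 708 and 166 in the null. At 50 weeks chemokine, cytokine and mast cell medians turned to -0.0164, -0.145 and -0.116. Without a filter on signal, whose extra genes lie near background, both age contrasts called 0; 2-fold counts were 1871 and 2293, 1903 and 2487, and 957 and 2793, 4-fold 479 and 407, 474 and 589, and 180 and 607, at all ages 177 and 209, and between ages 3830, 3868 and 3588 in the wild type and 3430, 4699 and 2730 in the null. Cytokine, B cell and mast cell medians at 50 weeks were -0.418, -0.554 and -0.338. Restricted to genes above background on all 6 arrays, which leaves out the Y-linked Eif2s3y and Ddx3y, both age contrasts called 0. Enteric neurons stood at -0.00179 at 5 weeks and cytokines at -0.00658 at 50 weeks. With the mean of a gene's probes, growth factors stood at -0.0389 at 50 weeks. The intensity trend called 28 and 13 genes. An estimated correlation called 0 lists either way. Fry called 1 list higher (fibroblasts) and 1 lower (circadian clock). Under the filter on wild-type spread, 2-fold counts were 181 and 278, 265 and 438, and 115 and 356, 4-fold 13 and 8, 25 and 18, and 14 and 15, and at all ages 21 and 33.

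The arrays of an age form a pair, fitted as a block by the age term. Without that block, limma called 4 genes higher and 2 lower, and camera 3 lists lower. With 1 pair left out at a time, 9 to 11 lists were higher and 3 to 5 lower, and the smooth muscle mean ranged from -0.913 to 0.984.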

Other observations

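The older null arrays resembled each other most. Between the null mice of 10 and 50 weeks 538 genes were at least 2-fold apart, the fewest of any pair of arrays. The null mouse of 5 weeks differed from the wild-type mice of 10 and 50 weeks at 855 and 925 genes, fewer than from the wild-type mouse of its own age (1377). The null mouse of 10 weeks likewise differed from the wild-type mouse of 50 weeks at 901 genes and from that of 10 weeks at 1636. The null mouse of 50 weeks went the other way. It differed from the wild-type mouse of its own age at 1078 genes, and from those of 5 and 10 weeks at 2903 and 2167. These counts were not tested.

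Probes of one gene went opposite ways, each by at least 0.5 on the log2 scale, for Igf1, the insulin-like growth factor, at 5 weeks (-0.52 to 0.98), and for Pigr, the receptor that carries antibodies across epithelium (-1.15 and 2.21). Short of that rule, probes also lay far apart or had opposite signs for the spindle gene Tpx2 at 5 weeks (-0.24 and 0.94), for Anxa8 at 10 weeks (-0.16 and 1.37), and for the keratins Krt10 at 10 weeks (-1.57 and 0.32) and Krt13 at 50 weeks (-3.72 and -0.14).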
